A study of Mus musculus with 4 samples.

How the data were processed

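RNA of mouse skin selected with oligo(dT) was made into TruSeq libraries, per the labels, and 4 libraries were analysed, 2 per genotype. The group of each library and its number, 2 or 3, come from the sample titles; the table's columns named Ctr were matched to the floxed titles because these are the only group besides cKO. The deposited table holds 1 row per Ensembl gene with estimated counts per library, FPKM per library and the authors' comparison.

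The counts are expected counts that the authors estimated, per the submitters' processing notes with RSEM; all are whole numbers in the deposited table. The FPKM values per library were computed by the authors, per the file headers, and were used in an alternative test only. The log2 fold change in the deposited table is the authors' value of cKO over control. The p-value and false discovery rate of each gene are also the authors', and edgeR is named in the submitters' processing notes; which of its tests was run is not given in the sources used here. The notes name the genome build mm8; the aligner, the annotation release and the strand setting are not given in the sources used here. Of the 47725 identifiers in the table, 98.9% match GENCODE M21, an annotation of the later build GRCm38, so no coordinates are printed and that annotation was used for names and for which genes neighbour each other. Strand is not stated to have been used, so reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes may have been split between copies. Another 4 lines of the table were empty and were not analysed here. A spreadsheet had turned 27 symbols into dates, and these were replaced through the identifier. Where several identifiers share a symbol, the one that M21 gives this symbol was taken for the lists, then the one with the highest count, a rule chosen after the data were seen.

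The counts summed to 15837136 to 23407731 per library, and the most abundant gene, mt-Co1, took 1.24% to 1.95%. Replicates of a group differed by far more than sampling noise, with a chi-square per gene of 24.2 in control and 93.6 in cKO, so the columns are not copies of one library. Counting intervals are exact Clopper-Pearson intervals at the 95% level. Intervals and floors of 3 counts cover counting error only.

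Genes were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1). The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) of cKO against control with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The biological coefficient of variation was 0.284. CPM values are TMM-scaled, and SD is between the 2 libraries of a group. SE is the absolute log2 fold change before edgeR's shrinkage, divided by the square root of the quasi-likelihood F statistic. The log2 fold changes printed are those after shrinkage. Gene lists were tested with camera on log2 CPM with a prior count of 2, two-sided, with a preset correlation of 0.01 and adjustment over the lists with at least 3 tested members; camera with an estimated correlation and fry, which asks whether a list moves on balance one way, were run beside it. Of 18 lists past the threshold with the preset correlation, 0 passed with an estimated one. With 2 libraries per group the smallest unadjusted p of camera with an estimated correlation was 0.0134, for the neutrophil list. The power of this test was not measured in simulated data. A call lost there therefore does not by itself decide whether a list changed. In fry 5 of the 18 lists passed. These were the IL-17, IL-23, IL-36 and IL-1 axis (fry adjusted p = 0.00505), the neutrophil list (0.00736), and the antimicrobial, stress keratin and fibroblast lists (each 0.0114). The other 13 lost their call in fry as well.

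Before the data were examined, 30 gene lists were fixed, 6 as core lists and 24 as other lists, with the test, the alternatives and the rule for named genes. That rule takes Ppp6c; the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 5 CPM in the higher group, both cKO libraries beyond both control libraries and no predicted or clone name; and the 3 members of each core list and the 2 of each other list with the smallest adjusted p. Core list members counted in a paragraph may also be named. Of the genes that the rule takes, 2 are not reported here. Another 5 lists were written after the values were seen.

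The scripts were tested on simulated data: counts for the 17440 tested genes were drawn from the real means, library sizes and dispersions, with 200 genes changed in each of 3 runs of cKO against control, and once with none changed. The quasi-likelihood test recovered 4% of genes changed 2-fold, 64% of those changed 4-fold, 90% of those changed 8-fold and 93.3% of those changed 16-fold, and 9.16% of its calls were false, above the nominal 5%. The share of false calls was 8.37% for limma voom, 23.1% for the quasi-likelihood test with the replicate block, 29.6% for the edgeR exact test and 33.9% for DESeq2. With no gene changed, 17117 genes passed the filter, and 5 were called by the quasi-likelihood test, 33 by the exact test, 42 by DESeq2, 0 by voom and 7 with the replicate block. Of 200 random lists of 20 genes, 2.5% had a camera p under 0.05 with the preset correlation and 0% with an estimated one. The simulated genes were drawn independently of each other. These shares therefore do not cover lists whose genes vary together, as the hair follicle and cell cycle genes did.

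The alternatives were median-of-ratios factors, library size alone, TMM without the muscle, adipocyte and hair follicle lists, 2 other filters, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, the edgeR exact test, limma voom, limma trend on log2 FPKM with pseudocounts of 1 and 0.1 over genes averaging at least 1 FPKM, the authors' deposited values, and stricter thresholds. The alternatives written for a table without counts were not needed. With a library left out, the lone library of its group is assumed to vary like the others. The spread then comes from the pair left whole, and the cKO pair differed more than the control pair (chi-square per gene of 93.6 against 24.2). The number of calls with a library left out therefore also depends on which pair remains.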

Results

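Messenger RNA was sequenced from whole skin of 17-week-old C57BL/6J mice of 2 genotypes. Control mice carried floxed alleles of Ppp6c, the gene of the catalytic subunit of protein phosphatase 6, written Pp6fl/fl in the labels. The other group is labelled cKO, and the series title pairs the floxed allele with K5, read here as the promoter of keratin 5, a gene of basal keratinocytes. Each group had 2 libraries, numbered 2 and 3 in the labels. The deposited counts summed to 23407731 and 22334208 in control replicates 2 and 3, and to 15837136 and 17459413 in cKO replicates 2 and 3. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

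The first question was whether the targeted transcript differed. Ppp6c (ENSMUSG00000026753) stood at 57.8 and 61.8 CPM (TMM-scaled) in the control libraries and at 62.1 and 50.1 CPM in cKO replicates 2 and 3. Its log2 fold change was -0.09 ± 0.16 (SE, n = 2 per group, edgeR quasi-likelihood adjusted p = 0.81). A count over the whole gene in whole skin, where many cells lie outside the keratin 5 lineage, does not show whether the floxed part was deleted, so the cKO label rests on the titles alone. The other members of the holoenzyme list did not pass either: 0 of 7 subunit genes were called by edgeR quasi-likelihood, 0 had an unadjusted p under 0.05, and DESeq2, the edgeR exact test and limma voom called 0. The regulatory subunit gene Ppp6r1 had a log2 fold change of -0.23 ± 0.14, and the scaffold gene Ankrd28 one of 0.34 ± 0.21. The median of the list was -0.07 and its camera adjusted p 0.979; the direction turned with median-of-ratios factors, without control replicate 3 and without cKO replicate 2 (camera adjusted p = 0.983, 0.982 and 0.829). Ppp6c itself had a log2 fold change of 0.062 without cKO replicate 3.

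Of 17440 genes tested, 190 differed between the groups, 129 higher and 61 lower in cKO (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Among the called genes the median log2 fold change was 2.76 for those higher and -2.53 for those lower, and the smallest absolute value was 1.2. In all 190 both cKO libraries lay beyond both control libraries, as did 52.9% of all tested genes, where chance gives 33.3%. In the same test 3489 of the 17440 genes had an unadjusted p under 0.05. Counts at that level in the lists below are to be read against this share. Without control replicate 2 or without control replicate 3 the same test called 0 genes, so each gene given below as risen or fallen lost its call. It called 1664 genes without cKO replicate 2 and 986 without cKO replicate 3, both times including all 190. DESeq2 called 1769, the edgeR exact test 1780, and the authors' deposited comparison 1620 genes, each including all 190; limma voom called 200, of which 162 were shared.

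Among called genes that reached 5 CPM in cKO and have no predicted or clone name, the 6 largest increases were in Spink7, Sprr2b, S100a9, S100a8, Irg1 and Clec4d. S100a9 and S100a8, which encode the subunits of calprotectin, rose from 3.81 ± 1.72 to 684 ± 246 CPM and from 1.93 ± 0.86 to 299 ± 76.96 CPM (SD, n = 2). Their log2 fold changes were 7.48 ± 0.55 and 7.27 ± 0.45 (SE; edgeR quasi-likelihood adjusted p = 0.0397 and 0.0332). Irg1, the enzyme that makes itaconate, rose by 7.24 ± 0.79 on the log2 scale, and Clec4d, a myeloid lectin receptor, by 7.15 ± 0.47. Spink7, an epithelial protease inhibitor, had 2 counts in the control libraries together against 1135 in cKO, a scaled ratio of 817 with a 95% counting interval from 226 to 6760. Sprr2b, a small proline-rich envelope protein, had 1 count against 305, a ratio of 439 with an interval from 78.2 to 17400.

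Among called genes chosen in the same way from control levels, the largest decreases included those of Defb8, Serpina3j, Skint7, Mrgprb11-ps and Pyy. Defb8, a beta-defensin gene, fell from 86.8 ± 28.6 to 0.16 ± 0.22 CPM (SD, n = 2), a log2 fold change of -9.08 ± 0.81 (SE; edgeR quasi-likelihood adjusted p = 0.0429). Skint7, a member of an epidermal and thymic family of immunoglobulin-like proteins, fell from 39.7 ± 6.12 to 0.52 ± 0.02 CPM (log2 fold change -6.23 ± 0.27). Mrgprb11-ps, a pseudogene, had a log2 fold change of -6.19 ± 0.38 and Pyy, which encodes a peptide hormone, one of -6.15 ± 0.47. Serpina3j, one of a cluster of near-identical serpin genes among which reads may be shared, had 3 counts in cKO against 628 in control, a scaled ratio of 145 with a 95% counting interval from 49.5 to 707.

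**Figure D1:**
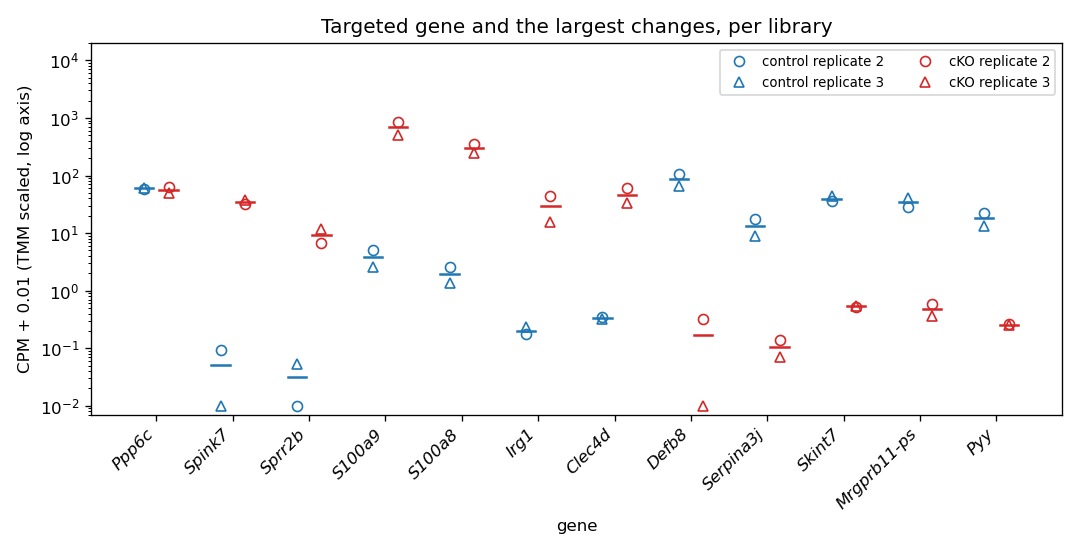
Level of the targeted gene and of 11 of the called genes with the largest changes in each library, as TMM-scaled CPM plus 0.01 on a log axis. Circles stand for replicate 2, triangles for replicate 3, and short lines for the group mean of 2 libraries. Ppp6c overlaps between control (blue) and cKO (red), whereas both cKO libraries lie beyond both control libraries for each of the other genes.

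Of the 15 tested antimicrobial and alarmin genes, 7 rose, 0 fell and 8 did not pass; adjusted over the list alone, 13 rose. Lcn2, the iron-siderophore binder lipocalin 2, rose from 5.01 ± 0.79 to 94.1 ± 5.27 CPM (SD, n = 2), a log2 fold change of 4.23 ± 0.19 (SE; edgeR quasi-likelihood adjusted p = 0.0244). S100a8, S100a9, Wfdc12, Chil1, Saa1 and Defb14 were the other called members. Saa3 averaged 1.29 CPM in control and 605 CPM in cKO without passing (edgeR quasi-likelihood adjusted p = 0.0601). Reg3g had 0 counts in control and 62 and 273 in cKO replicates 2 and 3, also without passing (edgeR quasi-likelihood adjusted p = 0.0879). Against a floor of 3 counts over the control group, its pooled cKO counts gave a scaled ratio of 161. That bound covers counting error only, not the difference between the cKO libraries. The median log2 fold change was 6.23 (camera adjusted p = 3.18e-13, and adjusted p = 0.235 with an estimated correlation).

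Of 17 tested neutrophil markers and chemokines, 6 rose, 0 fell and 11 did not pass, and adjusted over the list alone 16 were higher. Ly6g and Mpo, also among the 19 listed members, were not tested. Il1r2 went the other way, with a log2 fold change of -0.45 ± 0.19 without passing. The lectin receptors Clec4d and Clec4e, the formyl peptide receptor Fpr1, Trem1, the collagenase Mmp8 and the chemokine Cxcl3 were called. Clec4e rose by 7.01 ± 0.42 and Fpr1 by 6.68 ± 0.43 on the log2 scale. Cxcl5, a ligand of the neutrophil receptor Cxcr2, averaged 0.08 CPM in control and 57.8 CPM in cKO, a log2 fold change of 9.30 ± 1.57 that did not pass (edgeR quasi-likelihood adjusted p = 0.0733). The list's median log2 fold change was 6.11 (camera adjusted p = 3.09e-14, and adjusted p = 0.235 with an estimated correlation).

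Among stress keratins, small proline-rich and late envelope 3 genes, 11 of 28 tested genes rose, 0 fell and 17 did not pass; adjusted over the list alone, 24 rose. The called genes were Krt6a, Sprr1b, Sprr2b, Sprr2d, Sprr2h, Lce3b, Lce3c, Lce3d, Lce3e, Lce3f and Serpinb3b. Sprr2h rose from 4.85 ± 0.07 to 54.1 ± 0.63 CPM, Lce3e from 1.18 ± 0.32 to 48.6 ± 11.3 CPM and Lce3d from 1.89 ± 0.32 to 49.0 ± 13.6 CPM (SD, n = 2). Their log2 fold changes were 3.48 ± 0.16, 5.35 ± 0.33 and 4.70 ± 0.32. Reads can be shared within the Sprr2 and Lce3 clusters, so the split between neighbouring members is uncertain. Krt6b and Krt16, keratins of wounded and hyperproliferative epidermis, had log2 fold changes of 6.25 ± 0.98 and 4.56 ± 0.70 without passing (edgeR quasi-likelihood adjusted p = 0.068 and 0.0661). Over these genes the median log2 fold change was 4.57 (camera adjusted p = 3.56e-18, and adjusted p = 0.235 with an estimated correlation).

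In the IL-17, IL-23, IL-36 and IL-1 axis, 4 of 20 tested genes rose, 0 fell and 16 did not pass; adjusted over the list alone, 8 rose and 2 fell. Il1b rose from 9.30 ± 0.75 to 164 ± 45.7 CPM (SD, n = 2), a log2 fold change of 4.14 ± 0.26 (SE; edgeR quasi-likelihood adjusted p = 0.0332). Il1f6 and Il1f8, the IL-36 alpha and beta genes, rose by 3.37 ± 0.25 and 1.89 ± 0.16, and Il24 by 5.61 ± 0.57 on the log2 scale. Il17a and Il17f were too low to be tested. Over the list the median was 0.69 (camera adjusted p = 0.00219, and adjusted p = 0.423 with an estimated correlation).

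Of 24 tested urea cycle and polyamine genes, 1 rose, 0 fell and 23 did not pass; adjusted over the list alone, 4 rose and 1 fell. The called gene was Ass1, argininosuccinate synthase, at 21.4 ± 4.74 CPM in control and 76.1 ± 1.58 CPM in cKO (SD, n = 2), a log2 fold change of 1.83 ± 0.20 (SE; edgeR quasi-likelihood adjusted p = 0.048). Sat1, which acetylates spermidine and spermine, had a log2 fold change of 1.15 ± 0.18 and spermine synthase, Sms, one of -0.90 ± 0.16, neither passing. Arginase 1, Arg1, had 2.57 ± 0.49 (edgeR quasi-likelihood adjusted p = 0.0883). Across the list the median was 0.61 (camera adjusted p = 0.00171, and adjusted p = 0.613 with an estimated correlation).

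No cell cycle gene passed: 0 of 30 were called by edgeR quasi-likelihood, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2, by the edgeR exact test and by limma voom. Ccne1 had a log2 fold change of 1.21 ± 0.56, Cenpe of 0.79 ± 0.53 and Cdc20 of 0.49 ± 0.36. The median of the list was 0.48 (camera adjusted p = 0.0365, and adjusted p = 0.922 with an estimated correlation), and its direction turned without control replicate 3 (camera adjusted p = 0.982) and without cKO replicate 2 (camera adjusted p = 0.41). All 30 genes were higher in replicate 2 than in replicate 3 in both groups.

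Hair follicle keratin and shaft genes showed the same split by number: all 30 tested members were higher in replicate 2 than in replicate 3 in both groups. Their median log2 fold change in cKO was 2.58, but 0 of 30 passed in edgeR quasi-likelihood, against 13 at an unadjusted p under 0.05, 13 by DESeq2, 12 by the edgeR exact test, 21 in the authors' deposited comparison and 0 by limma voom. Krt33b had a log2 fold change of 3.08 ± 0.58 and Krtap3-2 of 1.69 ± 0.41. The camera adjusted p was 4.4e-08, and adjusted p = 0.623 with an estimated correlation. Of 8 melanocyte genes, 0 passed, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2, the exact test and voom (camera adjusted p = 0.586). Oca2 and Mlana had log2 fold changes of 1.97 ± 1.37 and 1.21 ± 1.04, and the list's direction turned without control replicate 3 and without cKO replicate 2 (camera adjusted p = 0.771 and 0.338), whereas it passed upward without cKO replicate 3 (0.0289). In replicate 2, 7 melanocyte genes in control and 8 in cKO exceeded replicate 3.

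Of 27 tested terminal differentiation genes, 1 rose, 0 fell and 26 did not pass; adjusted over the list alone, 10 rose and 2 fell. Flg, the filaggrin gene (ENSMUSG00000102439), rose from 174 ± 32.4 to 1143 ± 319 CPM (SD, n = 2), a log2 fold change of 2.72 ± 0.31 (SE; edgeR quasi-likelihood adjusted p = 0.049). The table holds 7 identifiers named Flg that can share reads; 2 of them were called, and their log2 fold changes ran from 2.51 to 2.72. Lce1m had -3.14 ± 0.39 (edgeR quasi-likelihood adjusted p = 0.0525). The list's median was 0.61 (camera adjusted p = 0.000917, and adjusted p = 0.61 with an estimated correlation).

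Basal keratinocyte genes and barrier lipid genes had medians of -0.02 and 0.04. In these lists 0 of 13 and 0 of 15 passed in edgeR quasi-likelihood. At an unadjusted p under 0.05 there were 7 and 8 genes, by DESeq2 5 and 4, by the exact test 5 and 3, and by voom 0 and 0. Adjusted over the list alone, 2 basal genes were higher and 2 lower, and 2 barrier lipid genes higher and 4 lower. Itgb1, an integrin gene, had a log2 fold change of 0.76 ± 0.15, and the sphingolipid enzymes Cers3 and Ugcg had 0.89 ± 0.14 and 0.84 ± 0.16, without passing. The camera adjusted p was 0.979 for the basal list and 0.93 for the barrier lipid list. Neither list had a settled direction: with library size alone the barrier lipid median was -0.035, and leaving out single libraries turned the basal list (without control replicate 2, 0.947; without cKO replicate 3, 0.462) and the barrier lipid list (without cKO replicate 3, 0.939). Of 16 sebaceous gland genes 2 fell, 0 rose and 14 did not pass, and adjusted over the list alone 11 fell. Scd3, a fatty acid desaturase, fell from 150 ± 20.5 to 5.09 ± 3.15 CPM (SD, n = 2), a log2 fold change of -4.88 ± 0.51. Acsbg1, an acyl-CoA synthetase, had -1.78 ± 0.17. The sebaceous median was -1.55 (camera adjusted p = 1.47e-07, and adjusted p = 0.613 with an estimated correlation).

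**Figure D2:**
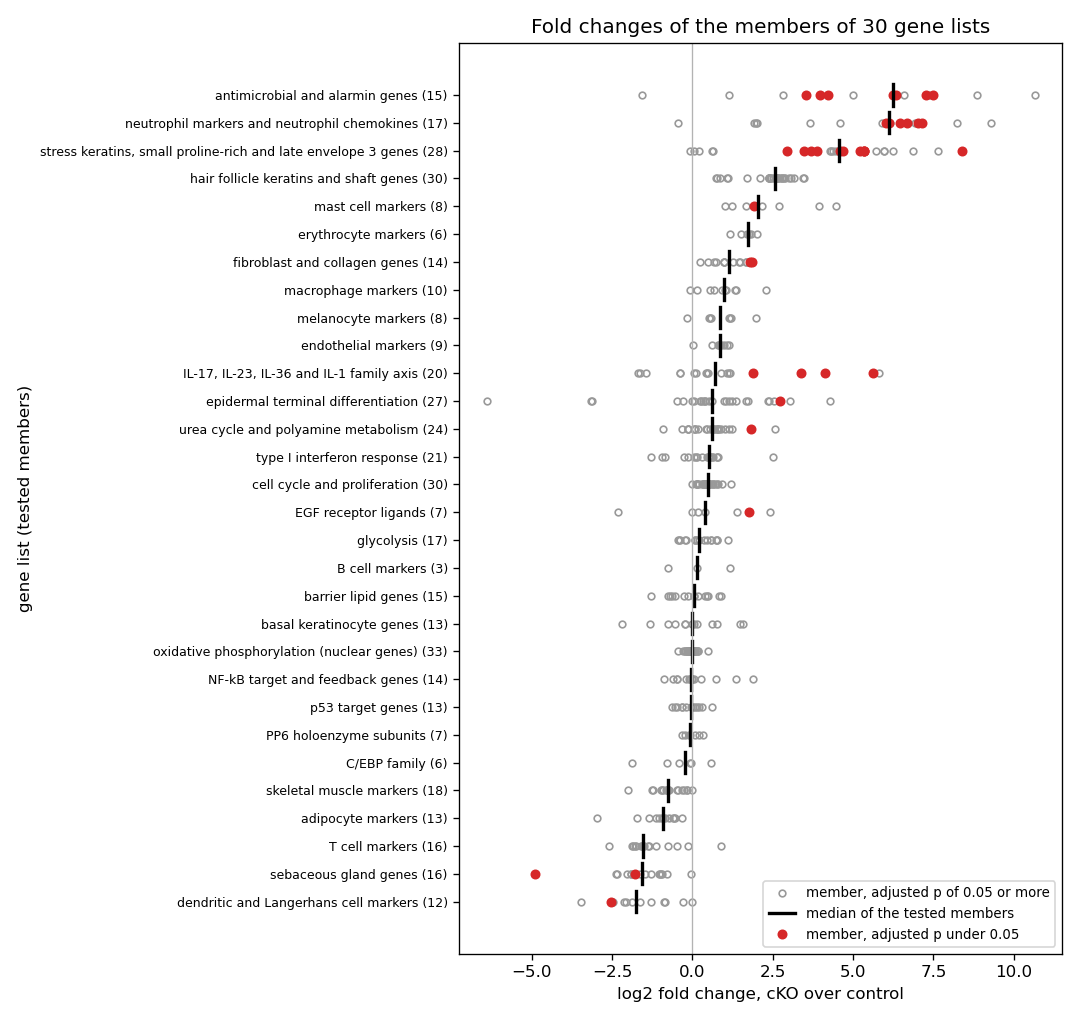
Log2 fold change of cKO over control for each tested member of the 30 gene lists, ordered by median. Each point is 1 gene, filled red where its edgeR quasi-likelihood adjusted p is under 0.05 and open grey otherwise. Black lines mark list medians, and the number of tested members stands beside each name. The highest medians are those of the antimicrobial, neutrophil and stress keratin lists at 6.23, 6.11 and 4.57, and the lowest is that of the dendritic and Langerhans cell list at -1.75.

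T cell markers had a median log2 fold change of -1.52 with 15 of 16 members negative. In edgeR quasi-likelihood 0 of 16 passed, against 12 at an unadjusted p under 0.05, 5 by DESeq2, 8 by the exact test and 0 by voom, and 8 fell adjusted over the list alone. Cd3g, a chain of the T cell receptor complex, had -1.85 ± 0.31 and Cd8a -2.60 ± 0.54 (list camera adjusted p = 6.3e-07, and adjusted p = 0.61 with an estimated correlation). Of 12 dendritic and Langerhans cell markers, 1 fell, 0 rose and 11 did not pass, and 7 fell adjusted over the list alone. Cd209a, a lectin of dermal dendritic cells, fell from 64.4 ± 19.1 to 11.1 ± 0.80 CPM (SD, n = 2), and H2-Ab1, an MHC class II chain, had a log2 fold change of -2.14 ± 0.37 without passing. That list's median was -1.75 (camera adjusted p = 6.62e-05, and adjusted p = 0.613 with an estimated correlation). Of its 12 members, 0 in control and 1 in cKO were higher in replicate 2 than in replicate 3. Among the 16 T cell markers there were 1 and 4 such genes.

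Of 8 mast cell markers, 1 rose, 0 fell and 7 did not pass, and 7 were higher adjusted over the list alone. Cpa3, a mast cell protease, rose from 27.4 ± 5.49 to 103 ± 16.5 CPM (SD, n = 2), and Fcer1a, a chain of the IgE receptor, had a log2 fold change of 3.95 ± 0.48 (edgeR quasi-likelihood adjusted p = 0.0525). The median was 2.05 (camera adjusted p = 1.09e-06, and adjusted p = 0.61 with an estimated correlation). The macrophage list had a median of 0.98, with 0 of 10 passing in edgeR quasi-likelihood, 6 at an unadjusted p under 0.05, 6 by DESeq2, 6 by the exact test and 0 by voom, and 6 higher adjusted over the list alone. The complement gene C1qb had 1.32 ± 0.17 and the Fc receptor gene Fcgr1 2.28 ± 0.32 (list camera adjusted p = 8.79e-05, and adjusted p = 0.613 with an estimated correlation). Of 3 B cell markers tested, 0 passed, 0 had an unadjusted p under 0.05 and DESeq2, the exact test and voom called 0 (camera adjusted p = 0.908). Blk had 1.17 ± 0.58 and Fcrla -0.75 ± 0.65; the list passed without control replicate 3 (0.0229) and turned without cKO replicate 3 (0.669).

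Of 14 fibroblast and collagen genes, 2 rose, 0 fell and 12 did not pass, and 10 were higher adjusted over the list alone. The type V collagen genes Col5a2 and Col5a1 rose from 188 ± 7.54 to 675 ± 0.14 CPM and from 151 ± 12.3 to 523 ± 91.4 CPM (SD, n = 2), by 1.84 ± 0.16 and 1.79 ± 0.20 on the log2 scale. Across all members the median was 1.13 (camera adjusted p = 9.28e-07, and adjusted p = 0.235 with an estimated correlation). The endothelial list had a median of 0.85. In edgeR quasi-likelihood 0 of 9 passed, against 6 at an unadjusted p under 0.05, 3 by DESeq2, 3 by the exact test and 0 by voom, with 3 higher adjusted over the list alone. Emcn had 1.15 ± 0.26 and Vwf 1.06 ± 0.25 (list camera adjusted p = 0.00165, and adjusted p = 0.623 with an estimated correlation).

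Adipocyte and skeletal muscle markers had medians of -0.90 and -0.75, and 0 of 13 and 0 of 18 passed in edgeR quasi-likelihood. At an unadjusted p under 0.05 there were 6 and 1 genes, by DESeq2 3 and 1, by the exact test 2 and 0, and by voom 0 and 0; adjusted over the list alone 2 adipocyte genes fell. Pck1 and Lep, the leptin gene, had -2.97 ± 0.45 and -1.73 ± 0.26, and the myosin and actinin genes Myh2 and Actn3 had -2.003 ± 0.73 and -1.24 ± 0.61. Muscle genes took 1.43% and 2.15% of the counts in the control libraries, 0.31% in cKO replicate 2 and 1.92% in cKO replicate 3. Of the 18 muscle markers, 0 were higher in replicate 2 than in replicate 3, in control and in cKO alike. The camera adjusted p was 0.000153 for adipocyte and 0.0126 for muscle markers, and adjusted p = 0.613 and 0.813 with an estimated correlation. Without cKO replicate 2 the muscle list lay in the other direction (camera adjusted p = 0.511). Of 6 erythrocyte markers, 0 passed, 0 had an unadjusted p under 0.05 and DESeq2, the exact test and voom called 0 (camera adjusted p = 0.141). Alas2 and Hbb-bt had 1.70 ± 0.93 and 1.77 ± 1.01, but -0.145 and -0.338 without cKO replicate 3. The erythrocyte list passed without cKO replicate 2 (0.00575) and without control replicate 3 (0.0306), and turned without cKO replicate 3 (0.939).

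Signalling and metabolic lists held few calls. Among 7 EGF receptor ligands 1 rose, 0 fell and 6 did not pass, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.141). Hbegf rose from 13.0 ± 0.52 to 44.3 ± 5.15 CPM (SD, n = 2), a log2 fold change of 1.77 ± 0.17, whereas Btc, betacellulin, had -2.32 ± 0.56 without passing. Glycolysis genes had a median of 0.22, with 0 of 17 passing in edgeR quasi-likelihood, 6 at an unadjusted p under 0.05, 4 by DESeq2, 2 by the exact test and 0 by voom, and 5 higher adjusted over the list alone. Slc16a3 and Slc2a1, transporters of lactate and glucose, had 1.09 ± 0.16 and 0.78 ± 0.14. The list's camera adjusted p was 0.0402, and adjusted p = 0.623 with an estimated correlation. The call was lost without control replicate 2 (camera adjusted p = 0.243) and without cKO replicate 3 (0.612).

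In the remaining lists edgeR quasi-likelihood called 0 of 14 NF-kB target genes, 0 of 21 interferon response genes, 0 of 6 C/EBP genes, 0 of 13 p53 targets and 0 of 33 nuclear oxidative phosphorylation genes. At an unadjusted p under 0.05 there were 5, 3, 2, 1 and 2 genes in that order, against 3489 of all 17440 tested genes. DESeq2 called 2, 2, 0, 0 and 0, the exact test 2, 1, 0, 0 and 0, and voom 0 in each. Adjusted over the list alone, 1 NF-kB gene was higher. Bcl3 and Tnfaip3 had log2 fold changes of 1.88 ± 0.23 and -0.87 ± 0.21, Oasl1 and Ifih1 had 2.52 ± 0.57 and -0.96 ± 0.24, and Cebpe and Cebpb had -1.88 ± 0.67 and -0.78 ± 0.28. Sesn1 and Gadd45a had -0.64 ± 0.12 and 0.60 ± 0.25, and Ndufa4 and Ndufb3 had 0.50 ± 0.12 and -0.44 ± 0.13. The camera adjusted p was 0.911, 0.127, 0.282, 0.732 and 0.908 for these lists. Without cKO replicate 2 the interferon list passed upward (camera adjusted p = 0.0286), as it did without control replicate 3 (0.0191), and oxidative phosphorylation turned upward (0.0298), while without cKO replicate 3 it passed downward (0.0145). The NF-kB list turned without control replicate 3 (0.855) and without cKO replicate 2 (0.444), and the p53 list without cKO replicate 3 (0.825).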

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

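The list counts without cKO replicate 2, the 35-list test and the choice among identifiers sharing a symbol were added after the data were seen. With 2 libraries per group, the count of called genes depended on the test, and the cause was not tested. Against 190 (129 higher, 61 lower), there were 883 (494, 389) with no filter beyond a count above 0, 1769 (1031, 738) with DESeq2, 1780 (971, 809) with the edgeR exact test, 1620 (937, 683) in the authors' deposited table and 307 with limma trend on log2(FPKM + 1), of which 139 lower; library size alone gave 113 lower. At an adjusted p under 0.01 there were 0 (0, 0). Leaving out 1 library gave 0 to 1664 genes (0 to 940 higher, 0 to 724 lower). Median-of-ratios factors, TMM without 3 lists, the filter at 1 CPM, voom, limma trend on log2(FPKM + 0.1) and the fold threshold stayed within 1.5 times. Replicate numbers are shared between the groups but the labels do not say that they pair the libraries, and 2 pairs are too few to decide it from the data; deviations of libraries with the same number correlated at 0.414 over genes, and the replicate block gave 1177 genes (716 higher, 461 lower), all 190 included. Of the 30 hair follicle genes the replicate block called 24, against 0 without it. In simulated data 23.1% of the calls with this block were false, but those data held no difference by replicate number. That share therefore need not hold for these genes.

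Ppp6c did not pass under any of 16 alternatives, with log2 fold changes from -0.257 to 0.062, the last without cKO replicate 3. Of 18 lists past the threshold, 0 remained with an estimated correlation and 5 in fry; with a library left out 17 to 20 of all lists passed. Of the 18, these included 17 without control replicate 2, 17 without control replicate 3, 16 without cKO replicate 2 and 17 without cKO replicate 3.

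Among the named genes 75 could be compared with most alternatives, and 30 lost their call without control replicate 2 and 30 without control replicate 3. Of those that turned, Cenpe ran from -0.03 (without cKO replicate 2) to 1.321 with a library left out, Oca2 from -0.087 to 4.898, Mlana from -0.873 to 2.039, Alas2 from -0.145 to 2.48 and Hbb-bt from -0.338 to 2.597 on the log2 scale.

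Directions turned in 11 lists, given as camera adjusted p. With a library left out, cell cycle ran from 4.76e-06 to 0.982, PP6 subunits from 0.829 to 0.982, basal keratinocyte from 0.314 to 0.947, barrier lipid from 0.768 to 0.947, NF-kB from 0.444 to 0.855, p53 from 0.34 to 0.825, oxidative phosphorylation from 0.0145 to 0.982, B cell from 0.0229 to 0.704, muscle from 1.7e-09 to 0.511, melanocyte from 0.0289 to 0.771 and erythrocyte from 0.00575 to 0.939. PP6 subunits turned with median-of-ratios factors (0.983), and basal keratinocyte with library size alone (0.991), the replicate block (0.987) and fry (0.935). With the replicate block glycolysis lost its call (0.0839), and 2 other lists gained one.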

Other observations

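The 5 lists below and all tests of explanations but that of strain DNA were chosen only after the result was seen. The hair follicle and T cell lists and their camera tests were fixed before. Of 11 Skint genes, 2 fell, Skint7 and Skint8, 0 rose and 9 did not pass in edgeR quasi-likelihood, and 11 fell adjusted over the list alone; the median log2 fold change was -2.71 (camera adjusted p = 3.9e-10, and adjusted p = 0.187 with an estimated correlation). Of 13 genes of dendritic epidermal T cells, 1 fell, Nkg7, 0 rose and 12 did not pass, and 9 fell adjusted over the list alone (median -1.61, camera adjusted p = 1.73e-08, and adjusted p = 0.187 with an estimated correlation). Of 10 MHC class II genes edgeR quasi-likelihood called 0, against 10 at an unadjusted p under 0.05, 9 by DESeq2, 9 by the exact test and 0 by voom, and 10 fell adjusted over the list alone. Their median was -1.98 (camera adjusted p = 3.35e-07, and adjusted p = 0.225 with an estimated correlation). These genes also split by number: 0 of 10 were higher in replicate 2 than in replicate 3, in control and in cKO alike.

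Of 12 matrix metalloproteinase and wound genes, 3 rose, 0 fell and 9 did not pass in edgeR quasi-likelihood, and 11 rose adjusted over the list alone (median 3.02, camera adjusted p = 3.9e-10, and adjusted p = 0.143 with an estimated correlation). Spp1, osteopontin, rose from 5.01 ± 0.21 to 123 ± 17.1 CPM (SD, n = 2), with Plaur and Timp1 the others. Of 19 NRF2 targets, 2 rose, 0 fell and 17 did not pass, and 8 rose and 1 fell adjusted over the list alone (median 0.50, camera adjusted p = 0.00023, and adjusted p = 0.143 with an estimated correlation). The called genes were the cystine transporter Slc7a11 (log2 fold change 5.10 ± 0.32) and the glutathione transferase Gsta4 (3.48 ± 0.32). Krt77, singled out after its values were seen, stood at 5997 and 5812 CPM in control and 139 and 0.955 CPM in cKO without passing (edgeR quasi-likelihood adjusted p = 0.225). Each call named in these paragraphs was lost without control replicate 2 or 3, where edgeR quasi-likelihood called 0 genes.

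Hair follicle genes had a median log2 fold change of 2.58 and were higher in replicate 2 of both groups in 30 of 30; both cKO libraries lay above both controls in 21 of 30, and the camera call was lost with an estimated correlation (adjusted p = 0.623). More epidermis and less muscle and fat would raise basal keratinocyte genes alike, but the hair follicle median exceeded theirs by at least 2.59 on the log2 scale. Scaling moves both lists alike, so the 4 scalings used add nothing to this gap. A hair cycle stage differing between animals apart from the genotype cannot be told apart from the genotype: the median gap between replicates was 2.09 in control and 1.81 in cKO, against 2.88 between groups, with 2 libraries each. An effect of the genotype on the follicle stays open as well.

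T cell, Skint and MHC class II genes had medians of -1.52, -2.71 and -1.98, few of them called, and their camera calls were lost with an estimated correlation (adjusted p = 0.61, 0.187 and 0.225). Dilution by a larger keratinocyte share would lower markers of other cells too. The lowest median of the macrophage, mast cell, endothelial and fibroblast lists was 0.85, but the adipocyte and skeletal muscle medians were -0.90 and -0.75. Each of these lists can also change for its own reasons, so they cannot decide on dilution of the T cell and MHC class II genes. The Skint family is epidermal and thymic, so a larger keratinocyte share would not by itself lower it. A scaling factor moves all genes of a library alike. It cannot set these 3 lists apart from the median of all genes, at -0.001, or from the macrophage, mast cell, endothelial and fibroblast lists. The highest of the 3 list medians over 4 scalings was -1.5. Whether the absolute level fell stays open, since these scalings shifted the median of all genes by only -0.066 to 0.019. A change in these cells or in their transcripts with the genotype stays open, as do other differences between the animals, which were not tested.

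Nearly lost in cKO, with a log2 fold change of at most -5 and a control mean of at least 5 CPM, were 9 called genes on 7 chromosomes, among them Defb8, 9130204L05Rik, Paqr7, Ear2, Skint7, Mrgprb11-ps, Pyy and Serpina3j. DNA of another strain carried along with the targeted gene would place them near it. Of these genes, 0 were among the 100 tested genes nearest to Ppp6c. The control mice carried floxed alleles too, so such DNA may be shared by both groups, and this result cannot decide the question. DNA carried along elsewhere was not examined. At the depth of the cKO libraries, the control level would have given at least 138 counts per library for each. The bound of 5 CPM on the control mean made a high number certain in advance, so this was no separate test of lower depth. A group without males was argued against by Ddx3y, at 78 CPM or more before TMM scaling in all 4 libraries. The bound set for Xist, below 1 CPM in all 4 libraries, was not met (highest 1.49 CPM). The labels do not say that each library is a single animal, so Ddx3y alone does not exclude a different mix of sexes. DNA of another strain, a genotype effect and sharing of reads among Defb, Skint and Serpina3 relatives stay open.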
